A study of Mus musculus with 6 samples.

How the data were processed

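RNA of 6 samples from cultured mouse cells was measured on single-colour Affymetrix arrays: 2 of Id2-HPC, 2 of E2A-deficient pre-pro-B cells and 2 labelled EBF-deficient pre-pro-B cells. Per the labels' protocols, RNA was amplified and labelled with the manufacturer's small-sample procedure, which copies it in 2 rounds; such labelling starts at the 3-prime end and loses the 5-prime part of long transcripts. The deposited values are an intensity per probe set on a linear scale, from 3.88 to 24366, with array medians from 20.7 to 21.6. How the authors summarised probes, corrected background and scaled the arrays is not given in the sources used here. No detection calls were used, so levels near the lower end of the scale may be background.

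Each array held 45101 probe sets, of which 64 were controls. The platform annotation gave 34945 probe sets 1 gene symbol, 932 several and 9160 none; only the first were named. Symbols were compared with a reference gene table (assembly GRCm38.p6) through their Entrez identifiers: 204 probe sets had an identifier that was not in it, and 0 symbols changed. Intensities were brought to a common median, 16 was added, and log2 was taken. After this the quartiles of the arrays differed by 0.17 log2 units, above the tolerance of 0.1 set beforehand, so quantile normalization was applied. Folds are on the log2(intensity + 16) scale, which understates the change of dim genes. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18193 genes, with no filter on dim genes. The build behind the probe sets is not named, so no coordinates are given, and the reference table was used only for names, chromosome membership and gene neighbours.

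Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), in a single fit of all 6 arrays with group means only. The fit had 3 residual degrees of freedom per gene and 11.6 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and the 3 comparisons were Id2-HPC minus EBF-deficient, Id2-HPC minus E2A-deficient and E2A-deficient minus EBF-deficient. Gene lists were tested with camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 13 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The version with an estimated correlation also rests on the 3 residual degrees of freedom of the fit, which weakens it at any correlation. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Beside the counts over all genes, each list has the counts adjusted over the list alone. Of 423 listed symbols, 380 were measured, with 5 genes in 2 lists each (Bst2, Csf1, Gata2, Il6 and Kit).

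The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. The lists were early B lineage, Pax5-dependent and mature B cell, T lineage and Notch, natural killer and innate lymphoid, granulocyte and monocyte, dendritic cell, stem and progenitor, erythroid and megakaryocyte, mast cell and basophil, stromal feeder, cell cycle, interferon response, and immediate early and heat shock. Genes were named in each comparison if they were among the 8 highest or 8 lowest differences that were called, at least 2-fold and without overlap between arrays, leaving out predicted and clone-named genes; if they were Tcf3, Tcf4, Tcf12, Id1, Id2, Id3, Ebf1, Pax5, Foxo1, Gata3, Notch1 or Cebpa; if they were among the 4 called members of a list with the largest difference; or if they were Xist or Y-linked genes of the technical checks. Cd79a, Hes1 and Nrarp in Id2-HPC against EBF-deficient, and the genes named only in the closing section were chosen after their values were seen.

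The procedure was tested on simulated data with 200 changed genes among 18193. Noise was drawn independently for each gene with the variances of the fit. Recovery therefore does not show how the procedure handles other spread between cultures or technical differences between groups. Differences of 0.5 log2 units were recovered in 98.8% of cases for Id2-HPC against EBF-deficient, 96.2% for Id2-HPC against E2A-deficient and 98.8% for E2A-deficient against EBF-deficient, with 12, 12 and 8 false calls, and differences of 1 and 2 log2 units in 100% for each. Alternatives covered the choice of probe sets, a filter on dim genes, the scaling, the added constant, the variance model, the arrays in the fit, the threshold, the replicate number as a block and each array left out in turn. Fits without X- and Y-linked genes and without the stromal genes were added after seeing the data.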

Results

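Gene expression was measured in cultured mouse haematopoietic progenitors with 6 single-colour Affymetrix arrays, 2 for each of 3 groups. The first group was Id2-HPC, an uninduced progenitor line that carries a human Id2 transgene; Id2 is a protein that binds E proteins and blocks their attachment to DNA. The second group was E2A-deficient pre-pro-B cells, which lack the E proteins encoded by Tcf3. The third group was labelled EBF-deficient pre-pro-B cells, with a disrupted Ebf1, the gene of an early B-cell transcription factor. All cells were grown on the stromal feeder line S17 with interleukin 7, Flt3 ligand and stem cell factor, and the Id2-HPC cells were also depleted of small numbers of CD19-, CD25- and CD11b-bearing cells. That depletion and the cell type cannot be told apart in either comparison with Id2-HPC. The stated purpose of the series was to characterise Id2-HPC cells, so each reference culture was compared with them, and then both reference cultures with each other. Levels below are log2(intensity + 16), given as mean ± SD over the 2 arrays of a group, and differences are given with the standard error of the limma fit. The arrays of a group are called biological replicates in the labels, without a statement that they came from separate cultures or animals, so p-values measure only the spread between these arrays. Arrays of the same group correlated at r = 0.9977 to 0.9983 over all 45101 probe sets, and arrays of different groups at 0.9714 to 0.9764. The first principal component, with 53.2% of the variance, set the E2A-deficient arrays apart from the rest, and the second, with 42.2%, separated Id2-HPC arrays from those labelled EBF-deficient. Only 2 arrays per group limit the precision.

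The targeted genes were examined first. Tcf3 was at 8.99 ± 0.07 in Id2-HPC arrays, 5.35 ± 0.18 in E2A-deficient arrays and 9.34 ± 0.11 in the arrays labelled EBF-deficient, and all 3 of its probe sets were lowest in the E2A-deficient arrays. Ebf1 went the other way from its label: it was at 4.70 ± 0.05 in Id2-HPC arrays, 4.69 ± 0.02 in E2A-deficient arrays and 9.67 ± 0.03 in the arrays labelled EBF-deficient, and each of its 5 probe sets was higher there, by 2.78 to 4.97 log2 units over the higher of the other groups. The position of these probes relative to the disrupted part of Ebf1 is not known, so the signal does not decide whether the label is right, and every direction drawn from these arrays carries that doubt. Cd79a, a gene of the B-cell receptor complex that Ebf1 activates, was at 4.90 in Id2-HPC arrays, 4.88 in E2A-deficient arrays and 4.90 in the arrays labelled EBF-deficient, against a median of 5.22 over all probe sets. The brightest of the 3 mouse Id2 probe sets read 9.19 ± 0.20 in Id2-HPC arrays, 7.79 ± 0.06 in E2A-deficient arrays and 9.16 ± 0.13 in the arrays labelled EBF-deficient; whether it also reads the human transgene is not known. A dimmer Id2 probe set had another order, at 5.50, 5.71 and 6.27. The third lay under the median of all probe sets in each group, at 4.84, 4.55 and 4.71. Statements on Id2 therefore rest on the brightest probe set alone.

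Sex-linked transcripts and control transcripts also separated the groups. Xist, the RNA that silences an X chromosome in female cells, was at 5.14 ± 0.05 in Id2-HPC arrays, 11.40 ± 0.14 in E2A-deficient arrays and 11.08 ± 0.01 in the arrays labelled EBF-deficient. The Y-linked gene Eif2s3y was at 9.66 ± 0.19, 4.57 ± 0.08 and 8.79 ± 0.18 in the same order, so that the arrays labelled EBF-deficient carried both kinds of transcript. Kdm5d (7.44, 4.38 and 7.22) and Uty (6.88, 4.54 and 6.43), also Y-linked, followed Eif2s3y, while Ddx3y was not measured under that name. The 4 bacterial poly-A control transcripts, which are added to RNA before labelling, were high only in Id2-HPC arrays; the one called dap was at 10.0 there and at 4.71 in the other 4 arrays. Hybridisation controls did not split in this way. The 3-prime minus 5-prime difference of Actb, a measure of how far labelling reached along a transcript, was 1.94 in Id2-HPC arrays, 1.53 in E2A-deficient arrays and 1.65 in those labelled EBF-deficient, and that of Gapdh was 2.19, 2.00 and 1.84 in the same order. The presence of poly-A controls and the cell type therefore cannot be told apart in either comparison with Id2-HPC.

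**Figure D1:**
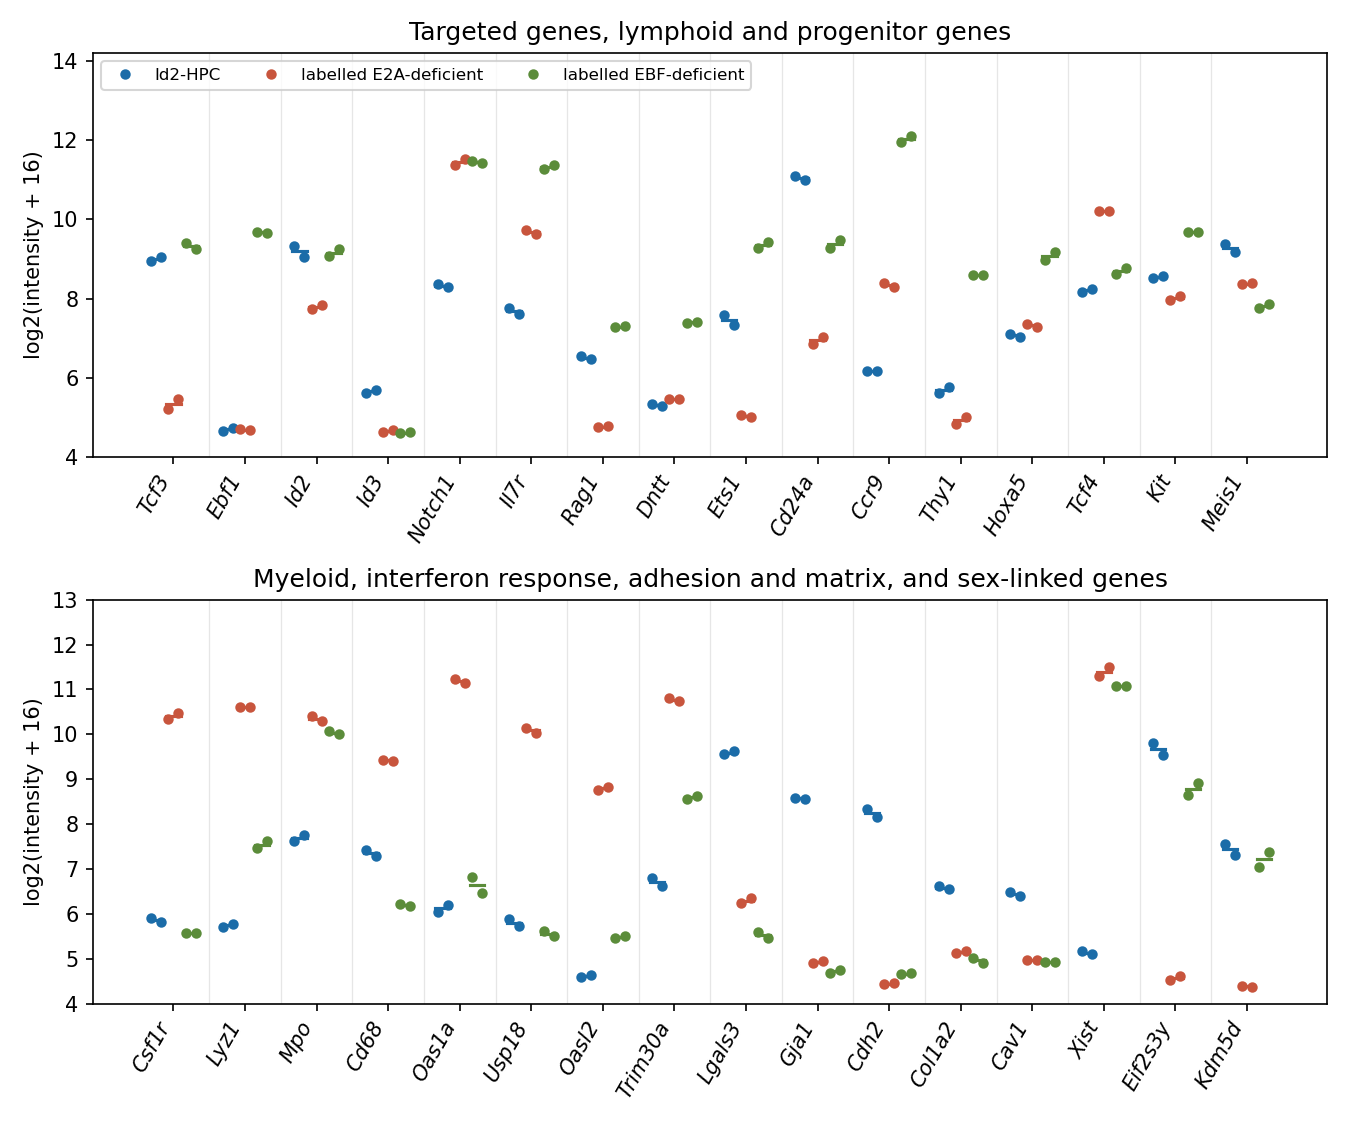
Level of 32 named genes on each of the 6 arrays, as log2(intensity + 16) on the vertical axis; each dot is an array, each short line a group mean, and colours give the group. Tcf3 is low only in the E2A-deficient arrays (5.35), whereas Ebf1 is high only in the arrays labelled EBF-deficient (9.67), and the 2 dots of a group lie close together.

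**Figure D2:**
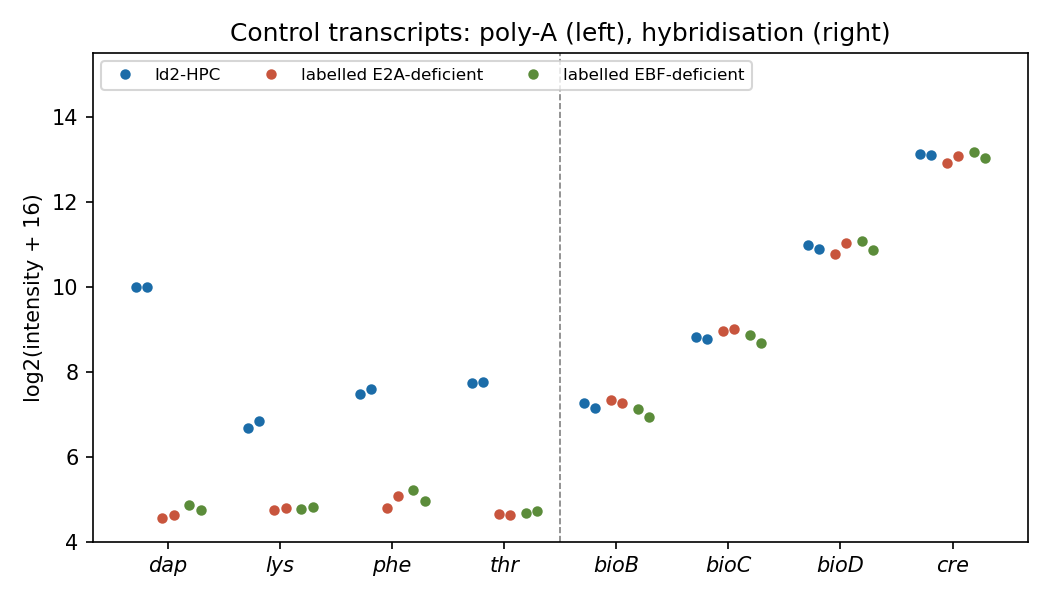
Level of 8 control transcripts on each array, as log2(intensity + 16); dots are arrays, and the dashed line separates the poly-A controls added before labelling from the hybridisation controls. Poly-A controls lie above the other arrays only in Id2-HPC, with dap at 10.0 against 4.71.

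Id2-HPC cells, compared with the cells labelled EBF-deficient, had lower levels of Notch1, Il7r and Ccr9 and higher levels of Gja1, Cdh2 and Lgals3. By camera with its preset correlation, the early B, mature B, T-lineage, dendritic-cell and interferon-response lists were lower and the cell-cycle and stromal lists higher, but each of these calls was lost with an estimated correlation (adjusted p from 0.0599 to 0.334). Notch1, the receptor that directs progenitors to the T lineage, was 8.7-fold lower (log2 difference −3.13 ± 0.07), and Il7r, the interleukin 7 receptor chain, was 12.4-fold lower (−3.64 ± 0.07). Ccr9, a chemokine receptor of thymus-seeding and dendritic cells, was 57.7-fold lower (−5.85 ± 0.08). The gap-junction protein gene Gja1 was 14.5-fold higher (3.86 ± 0.09), Cdh2, which encodes N-cadherin, was 11.9-fold higher (3.57 ± 0.09), and Lgals3, which encodes galectin-3, was 16.8-fold higher (4.07 ± 0.09). Gja1, Cdh2 and Lgals3 are not in the stromal list. Whether RNA of the S17 feeder cells or separate labelling contributed to their higher levels was not tested.

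Of 18193 genes, 6099 were called (limma, Benjamini-Hochberg adjusted p under 0.05), 3459 higher and 2640 lower in Id2-HPC; 629 of them differed at least 2-fold, 274 higher and 355 lower. The median absolute log2 difference of the called genes was 0.44, so most calls were small. The remaining genes among the 8 highest were Akr1c13, Emp1, Ifitm3, Anxa2 and Cobll1, with log2 differences from 2.90 to 3.72. The remaining genes among the 8 lowest were Xist, Ebf1, Igf2r, Irs1, Trgv1, Acss1 and Nav1, from −5.94 to −3.76; Trgv1 is a T-cell receptor gamma variable segment, and Irs1 an adaptor of insulin signalling.

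Of the 29 measured early B-lineage genes, 14 were lower in Id2-HPC, 4 were higher and 11 were not called, and the counts adjusted over the list alone were the same. Beside Ebf1 and Il7r, Dntt, the enzyme that adds nucleotides at antigen-receptor joins, was lower by a log2 difference of −2.10 ± 0.09 and the transcription factor Ets1 by −1.89 ± 0.10. The camera adjusted p of the list was 4.34e-05, and the adjusted p was 0.0599 with an estimated correlation. The Pax5-dependent and mature B-cell list had 6 of 22 members lower and 3 higher (7 and 3 adjusted over the list alone); Spib (−2.10 ± 0.09), Cd72 (−1.85 ± 0.10) and Ly86 (−1.84 ± 0.09) were lower, while Pax5 itself was at 5.02 and 4.97. Its camera adjusted p was 0.0185, the adjusted p was 0.334 with an estimated correlation, and across alternatives it ranged from 0.00603 to 0.277, with the call lost when only the brightest 60% of genes were kept, without a variance trend and at an adjusted p of 0.01.

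Of the 26 T-lineage and Notch genes, 11 were lower and 2 higher (12 and 2 adjusted over the list alone). The 2 higher were the Notch target genes Hes1 (0.46 ± 0.08) and Nrarp (0.37 ± 0.13), although Notch1 itself was lower. Thy1, a surface protein of T-lineage cells, was 7.5-fold lower and Ly6d, a marker of early B-lineage progenitors, 6.4-fold lower. The list had a camera adjusted p of 0.000276, and the adjusted p was 0.139 with an estimated correlation. Of 23 dendritic-cell genes, 14 were lower and 3 higher, with the same counts adjusted over the list alone; they included Bst2, an interferon-inducible surface protein (−2.41 ± 0.09), and the class II antigen-presentation gene H2-Aa (−1.94 ± 0.09). Camera gave this list an adjusted p of 2.56e-07, and the adjusted p was 0.0599 with an estimated correlation. Interferon-response genes were lower for 17 of 29 members and higher for 2 (17 and 5 adjusted over the list alone), with Trim30a at −1.88 ± 0.08 and Mx1 at −1.56 ± 0.11. The adjusted p by camera was 3.26e-06, and the adjusted p was 0.0599 with an estimated correlation.

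Cell-cycle genes were higher in Id2-HPC for 24 of 37 members and lower for 1 (26 and 1 adjusted over the list alone). The mitotic kinase genes Plk1 (1.13 ± 0.07) and Aurka (0.98 ± 0.07), the cyclin gene Ccne1 (0.93 ± 0.09) and Cdc20 (0.86 ± 0.07) led the list, whose median log2 difference was 0.33. For this list camera gave an adjusted p of 2.56e-07, and the adjusted p was 0.0599 with an estimated correlation. Stromal genes, chosen as markers of the feeder layer, were higher for 18 of 35 members and lower for 2 (19 and 2 adjusted over the list alone). Col1a2, which encodes a fibrillar collagen chain, was 3.1-fold higher, and Cav1, a gene of membrane caveolae, 2.9-fold higher. Acta2, a smooth-muscle actin gene, was 2.7-fold higher on a probe set shared by several transcripts, but the difference was −0.04 without such probe sets. The probe set then used lay near the lower end of the scale (4.61 in Id2-HPC arrays and 4.65 in those labelled EBF-deficient), so it cannot decide the direction. Pdgfrb, a growth-factor receptor gene, was 6.7-fold lower. The camera adjusted p was 3.26e-06, and the adjusted p was 0.0599 with an estimated correlation. These differences moved with the poly-A controls, which were at 10.0 for dap in Id2-HPC arrays and 4.71 in the others.

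The other lists did not pass the camera test in this comparison. Natural killer and innate lymphoid genes were higher for 10 of 31 members and lower for 5, as also when adjusted over the list alone (camera adjusted p = 0.743), with Tox, a regulator of innate and T-cell development, at 1.46 ± 0.09 and the lectin receptor gene Klrb1f at −1.78 ± 0.12. Granulocyte and monocyte genes were higher for 7 of 41 and lower for 10 (7 and 11 adjusted over the list alone; camera adjusted p = 0.122); the granule enzyme gene Mpo was 5.1-fold lower and the lectin gene Clec4d 4.5-fold higher. That p was 0.0484 without Id2-HPC replicate 2, and the list was also called with either scaling that left out quantile normalization. Stem and progenitor genes were higher for 8 of 33 and lower for 10 (9 and 11 adjusted over the list alone; camera adjusted p = 0.127): Meis1, a partner of Hox proteins, was 2.7-fold higher and Hoxa5 4.0-fold lower. Erythroid and megakaryocyte genes were higher for 2 of 23 and lower for 1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.603). Mast-cell and basophil genes were higher for 3 of 21 and lower for 2 (2 and 2 adjusted over the list alone; camera adjusted p = 0.879), with Cpa3, a mast-cell protease gene, 4.9-fold lower. Immediate early and heat-shock genes were higher for 12 of 30 and lower for 8 (13 and 9 adjusted over the list alone; camera adjusted p = 0.879), with Fos at −3.46 ± 0.07. Medians were above 0 and means below it for 4 of these lists, namely granulocyte and monocyte (0.03 and −0.17), stem and progenitor (0.01 and −0.14), mast cell and basophil (0.05 and −0.07) and immediate early (0.07 and −0.08), and their tests pointed down.

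Among regulators of the E protein system, Id3 was 2.1-fold higher in Id2-HPC (1.04 ± 0.05, adjusted p = 8.64e-10 by limma), Id1 was 0.36 ± 0.06 higher, and Id2 was not called on its brightest probe set (0.03 ± 0.09, adjusted p = 0.84 by limma) but was lower on a dimmer probe set (−0.77, adjusted p = 1.78e-05 by limma) and higher on the third (0.13, adjusted p = 0.0137 by limma). Tcf4, another E protein gene, was lower (−0.50 ± 0.07), and Gata3, a T-lineage factor, was lower (−0.50 ± 0.10). Foxo1 was not called (−0.06 ± 0.17). Tcf12 was not called on the probe set used (−0.17 ± 0.07), but other probe sets were called lower (−1.45 and −0.71) and higher (0.38), so its direction is uncertain. The calls of Tcf3 (−0.34 ± 0.09) and Cebpa (0.27 ± 0.09) were lost when Id2-HPC replicate 1 was left out, at −0.29 and 0.16, and when replicate 1 of the arrays labelled EBF-deficient was left out, at −0.27 and 0.24; Cebpa was also lost without replicate 2 of the latter, at 0.29.

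Id2-HPC cells, compared with E2A-deficient cells, had less RNA of interferon-response and of granulocyte and monocyte genes, and more of cell-cycle genes. The dendritic-cell and immediate early lists were also lower, and the innate lymphoid and stromal lists higher, by camera with its preset correlation, but these calls were lost with an estimated correlation (adjusted p from 0.065 to 0.0789). The antiviral enzyme gene Oas1a was 33.4-fold lower in Id2-HPC (−5.06 ± 0.10) and Usp18, a brake on interferon signalling, 19.6-fold lower (−4.29 ± 0.09). Csf1r, the receptor of the macrophage growth factor, was 23.1-fold lower (−4.53 ± 0.09). In the other direction, Cd24a, a surface protein of early lymphoid cells, was 17.1-fold higher (4.09 ± 0.09), and Ets1 was 5.4-fold higher (2.43 ± 0.10). Notch1 was 8.7-fold lower (−3.12 ± 0.07), by about the same amount as against the cells labelled EBF-deficient.

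In this comparison 6053 of 18193 genes were called by limma, 3541 higher and 2512 lower in Id2-HPC, with a median absolute log2 difference of 0.44; 780 differed at least 2-fold, 365 higher and 415 lower. The remaining genes among the 8 highest were Eif2s3y, Dynlt3, Akr1c13, Syce2, Prr13, Ctla2a and Ripk3, with log2 differences from 3.85 to 5.09; Ripk3 is a kinase of necroptosis. The remaining genes among the 8 lowest were Xist, Ly86, Lyz1, Trim30d and Oasl2, from −6.26 to −4.19. Ly86 is a partner of a toll-like receptor relative, and Lyz1 is a lysozyme gene whose probe set may also read its near-identical copy Lyz2.

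All 29 interferon-response genes were lower in Id2-HPC, also adjusted over the list alone, with a median log2 difference of −2.02. Oasl2 (−4.19 ± 0.09) and Trim30a (−4.06 ± 0.08) were among the members with the largest differences. By camera the adjusted p was 1.1e-34, and the call held with an estimated correlation (adjusted p = 0.00992). Granulocyte and monocyte genes were lower for 26 of 41 members and higher for 3 (27 and 3 adjusted over the list alone); beside Csf1r and Lyz1, Mpo was 6.3-fold lower and Lyz2 differed by −3.58 ± 0.10. The list had a camera adjusted p of 3.37e-12, and the call held with an estimated correlation (adjusted p = 0.0335). Itgam, the gene of CD11b, belongs to this list, and depletion of CD11b-bearing cells is described for Id2-HPC alone. Whether that depletion contributed to the lower myeloid genes was not tested. Of 23 dendritic-cell genes, 12 were lower and 3 higher (12 and 4 adjusted over the list alone), among them Bst2 (−3.23 ± 0.09), Tcf4 (4.0-fold lower), whose product directs plasmacytoid dendritic cells, and Siglech (−1.88 ± 0.12), a marker of those cells. Camera gave this list an adjusted p of 3.09e-05, and the adjusted p was 0.0789 with an estimated correlation. Immediate early and heat-shock genes were lower for 15 of 30 and higher for 4, with the same counts adjusted over the list alone; Fos was 15.8-fold lower and Atf3 4.6-fold lower, while the heat-shock gene Hspa1b was 4.2-fold higher. The adjusted p by camera was 1.67e-05, and the adjusted p was 0.0789 with an estimated correlation.

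Natural killer and innate lymphoid genes were higher in Id2-HPC for 14 of 31 members and lower for 3 (15 and 3 adjusted over the list alone). The chemokine genes Ccl5 (2.21 ± 0.09) and Xcl1 (1.75 ± 0.07), the granule gene Nkg7 (2.13 ± 0.07) and Tox (1.80 ± 0.09) were higher, and Id2, a member of this list, was 2.6-fold higher on its brightest probe set (1.41 ± 0.09), while another was not called (−0.21, adjusted p = 0.14 by limma) and the third was higher (0.28, adjusted p = 1.67e-05 by limma). For this list camera gave an adjusted p of 0.00036, and the adjusted p was 0.0789 with an estimated correlation. Cell-cycle genes were higher for 23 of 37 and lower for 0, as also adjusted over the list alone, with Aurka at 0.81 ± 0.07 and Cdc20 at 0.77 ± 0.07. The camera adjusted p was 8.82e-07, and the call held with an estimated correlation (adjusted p = 0.0402). Stromal genes were higher for 18 of 35 and lower for 0 (19 and 0 adjusted over the list alone): Cav1 was 2.8-fold higher, Col1a2 2.7-fold and Col6a1, another collagen gene, 2.3-fold. By camera the adjusted p was 8.82e-07, and the adjusted p was 0.065 with an estimated correlation. The poly-A controls were higher in the same arrays as the genes of these lists.

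The remaining lists did not pass. Early B-lineage genes were higher for 9 of 29 members and lower for 8, as also adjusted over the list alone (camera adjusted p = 0.879), with Rag1, the antigen-receptor recombinase gene, 3.3-fold higher and Il7r 4.0-fold lower; the median of the list was −0.04, its mean 0.18, and the test pointed down. Pax5-dependent and mature B-cell genes were higher for 2 of 22 and lower for 3, as also adjusted over the list alone (camera adjusted p = 0.0953; 0.049 without Id2-HPC replicate 2). T-lineage and Notch genes were higher for 10 of 26 and lower for 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.386). Notch1 was lower, whereas the Notch target genes Nrarp and Hes1 were higher by 0.75 ± 0.13 and 0.75 ± 0.08. Stem and progenitor genes were higher for 9 of 33 and lower for 9 (10 and 10 adjusted over the list alone; camera adjusted p = 0.805), with a median of −0.03, a mean of 0.01 and a test that pointed down; Tal1 (−1.67 ± 0.10) and Lmo2 (−1.32 ± 0.07), partners in a progenitor transcription complex, were lower. Mycn, in the same list, was 1.38 ± 0.08 higher on the probe set used and 0.52 on a dimmer one, but the third differed by −5.73, so its direction is uncertain. Erythroid and megakaryocyte genes were higher for 1 of 23 and lower for 1, as also adjusted over the list alone (camera adjusted p = 0.879). Mast-cell and basophil genes were higher for 3 of 21 and lower for 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.513).

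Id3 was 2.0-fold higher in Id2-HPC than in E2A-deficient cells (1.01 ± 0.05, adjusted p = 9.23e-10 by limma), and Id1 was not called (0.14 ± 0.06, adjusted p = 0.113 by limma; 0.0495 without E2A-deficient replicate 1). Pax5 was not called (−0.10 ± 0.06). Ebf1 was not called on the probe set used (0.02 ± 0.09), while of its 4 others 3 were called higher in Id2-HPC (0.53, 0.62 and 0.71). These 3 read 5.07 to 5.3 in Id2-HPC and 4.44 to 4.6 in E2A-deficient arrays, near or under the median of 5.22 over all probe sets. Tcf12 (0.02 ± 0.07) and Foxo1 (−0.04 ± 0.17) were not called either, but with other choices of probe set Tcf12 was at −0.35 and Foxo1 at 0.47, both called. Single Tcf12 probe sets were called lower (−1.26 and −0.75) and higher (0.33). The calls of Gata3 (0.38 ± 0.10) and Cebpa (−0.30 ± 0.09) were lost without Id2-HPC replicate 2, at 0.36 and −0.19, and without E2A-deficient replicate 1, at 0.34 and −0.21.

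E2A-deficient cells, compared with the cells labelled EBF-deficient, had more RNA of interferon-response genes. The granulocyte and monocyte and the immediate early lists were also higher, and the early B, T-lineage and innate lymphoid lists lower, by camera with its preset correlation, but these calls were lost with an estimated correlation (adjusted p from 0.0615 to 0.219). Csf1r was 28.3-fold higher (4.82 ± 0.09), Usp18 23.2-fold higher (4.54 ± 0.09), and Cd68, a lysosomal protein of macrophages, 9.3-fold higher (3.21 ± 0.08). Ets1 was 20.0-fold lower in E2A-deficient cells (−4.32 ± 0.10), Thy1 12.7-fold lower (−3.67 ± 0.10) and Jchain, the immunoglobulin joining chain gene, 37.9-fold lower (−5.24 ± 0.08). The poly-A controls were at the low end of the scale in both groups, and the stromal list did not separate them.

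Here 5716 of 18193 genes were called by limma, 2791 higher and 2925 lower in E2A-deficient cells, with a median absolute log2 difference of 0.42; 741 differed at least 2-fold, 352 higher and 389 lower. The remaining genes among the 8 highest were Oas1a, Lgmn, Dpp4, Tnfsf9, Gpr183 and Ly86, with log2 differences from 3.47 to 4.53; Lgmn is a lysosomal protease gene. The remaining genes among the 8 lowest were Ebf1, Trgv1, Syce2, Dynlt3, Igf2r and Cmah, from −4.99 to −4.34; Cmah makes a sialic acid of mouse cells.

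Interferon-response genes were higher in E2A-deficient cells for 27 of 29 members and lower for 1, as also adjusted over the list alone, with a median log2 difference of 1.75; Oasl1 (3.35 ± 0.10) and Oasl2 (3.31 ± 0.09) followed Usp18 and Oas1a. The list had a camera adjusted p of 3.75e-25, and the call held with an estimated correlation (adjusted p = 0.0161). Granulocyte and monocyte genes were higher for 21 of 41 and lower for 4 (25 and 4 adjusted over the list alone), with Lyz1 8.4-fold and Lyz2 6.7-fold higher. Camera gave this list an adjusted p of 2.24e-07, and the adjusted p was 0.0615 with an estimated correlation. Immediate early and heat-shock genes were higher for 13 of 30 and lower for 4 (14 and 6 adjusted over the list alone), with Atf3 (3.15 ± 0.10), Klf6 (2.40 ± 0.08), Jun (1.86 ± 0.11) and the heat-shock gene Hsph1 (1.66 ± 0.07) higher. The adjusted p by camera was 0.00404, and the adjusted p was 0.219 with an estimated correlation.

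Early B-lineage genes were lower in E2A-deficient cells for 13 of 29 members and higher for 2 (14 and 3 adjusted over the list alone), with Rag1 at −2.53 ± 0.09 and Cd24a at −2.43 ± 0.09. For this list camera gave an adjusted p of 1.74e-05, and the adjusted p was 0.0615 with an estimated correlation. T-lineage and Notch genes were lower for 13 of 26 and higher for 1 (13 and 2 adjusted over the list alone), among them Ly6d (−2.96 ± 0.10), Cd247, a signalling chain of the T-cell receptor (−1.71 ± 0.10), and the adaptor gene Lat (−1.06 ± 0.10). The camera adjusted p was 0.000148, and the adjusted p was 0.148 with an estimated correlation. Natural killer and innate lymphoid genes were lower for 18 of 31 and higher for 3 (18 and 4 adjusted over the list alone), with Ccl5 (−1.87 ± 0.09), Cd7 (−1.76 ± 0.11), Nkg7 (−1.66 ± 0.07) and Id2 (−1.37 ± 0.09) lower. By camera the adjusted p was 1.68e-05, and the adjusted p was 0.0626 with an estimated correlation.

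For each of the other 7 lists the camera adjusted p was 0.562. Dendritic-cell genes were higher for 10 of 23 and lower for 6, as also adjusted over the list alone, with a median of 0.10, a mean of −0.17 and a test that pointed up; Ccr9 was 12.9-fold lower, H2-Aa 7.4-fold lower and Itgax, an integrin gene of dendritic cells, 4.9-fold lower. Pax5-dependent and mature B-cell genes were higher for 4 of 22 and lower for 6 (6 and 7 adjusted over the list alone), with a mean of 0.05 and a test that pointed down. Stem and progenitor genes were higher for 8 of 33 and lower for 11 (10 and 11 adjusted over the list alone), with a median of 0.05, a mean of −0.15 and a test that pointed down; Gfi1b, an erythroid and progenitor repressor gene, was 5.4-fold lower and Egfl7 3.2-fold higher. Mycn was −2.07 ± 0.08 on the probe set used, −0.66 on a dimmer one and 5.97 on the third, so its direction is uncertain here too. Erythroid and megakaryocyte genes were higher for 3 of 23 and lower for 2, as also adjusted over the list alone. Mast-cell and basophil genes were higher for 1 of 21 and lower for 4, as also adjusted over the list alone, with Cpa3 5.6-fold and Kit, the stem cell factor receptor, 3.2-fold lower; the median was 0.02, the mean −0.15, and the test pointed down. Stromal genes were higher for 2 of 35 and lower for 2 (1 and 2 adjusted over the list alone), with a median of 0.05, a mean of −0.03 and a test that pointed up; Pdgfrb was 16.5-fold lower. Cell-cycle genes were higher for 11 of 37 and lower for 8 (11 and 9 adjusted over the list alone), with Ccne1 at 1.02 ± 0.09 and Mki67, a proliferation marker, at −0.54 ± 0.07.

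Tcf4 was 2.8-fold higher in E2A-deficient cells than in those labelled EBF-deficient (1.51 ± 0.07), Gata3 was lower (−0.88 ± 0.10), and Cebpa, a myeloid transcription factor, was higher (0.57 ± 0.09). Id3 (0.03 ± 0.05) and Pax5 (0.16 ± 0.06) were not called. Foxo1 was not called on the probe set used (−0.02 ± 0.17), but was lower on others (−0.40 and −0.35). Tcf12 was not called (−0.19 ± 0.07), except without replicate 2 of the arrays labelled EBF-deficient, at −0.24. Notch1 was not called on the probe set used (−0.01 ± 0.07) and was at 0.16, and called, as the mean of its probe sets. Xist was 0.32 ± 0.08 higher, a call lost without E2A-deficient replicate 2, at 0.22. The call of Id1 (0.22 ± 0.06) was lost without E2A-deficient replicate 1, at 0.17, and without replicate 2 of the arrays labelled EBF-deficient, at 0.20.

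**Figure D3:**
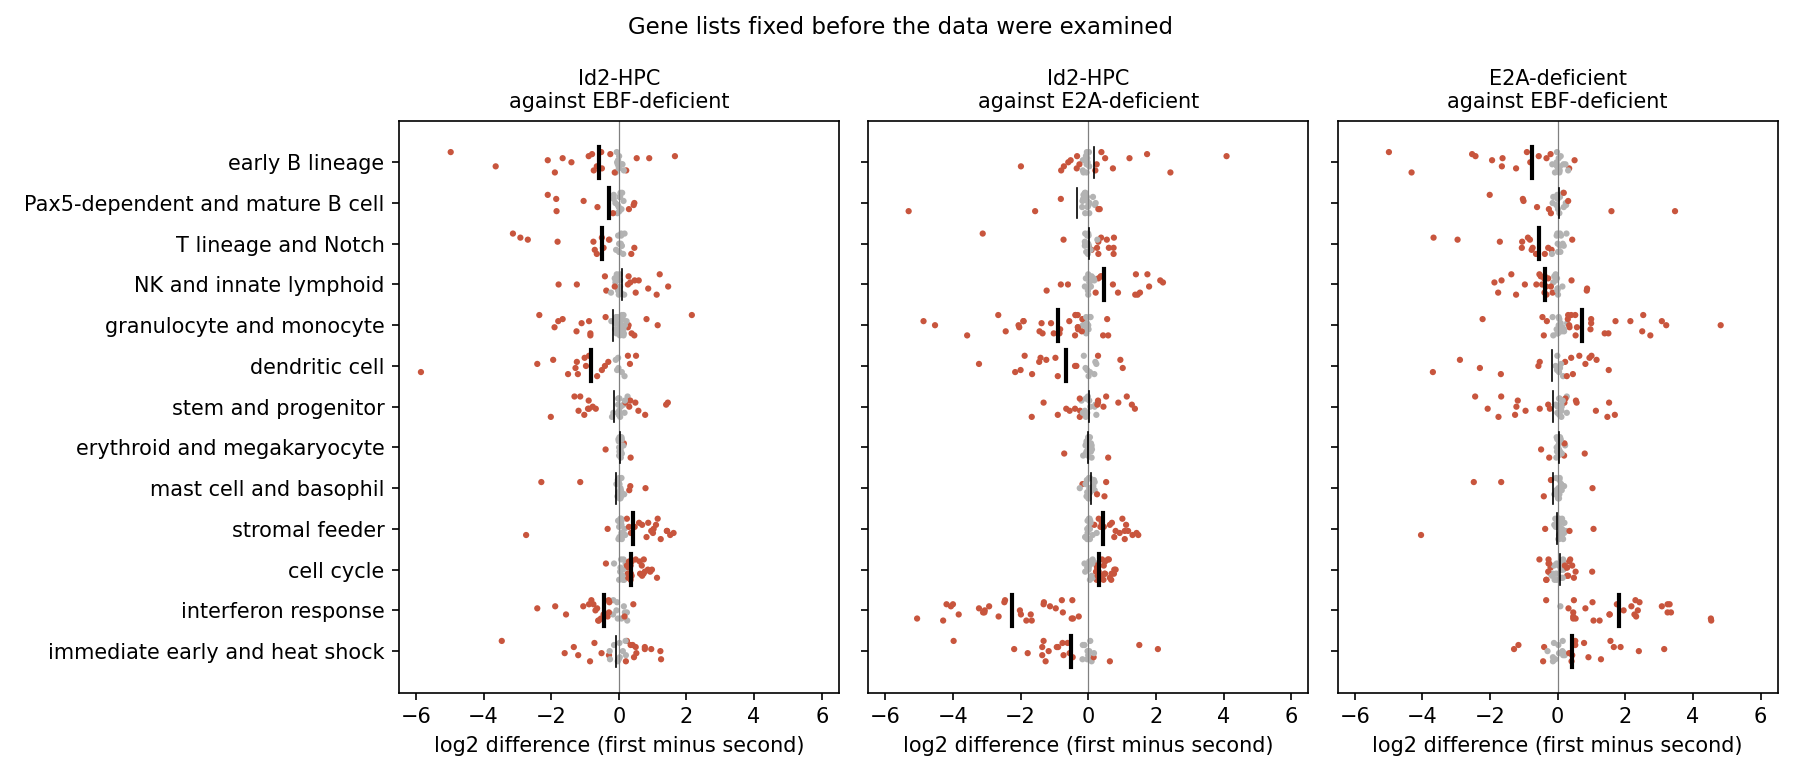
Log2 difference of each measured member of the 13 gene lists in the 3 comparisons, first group minus second; red dots are genes called by limma at an adjusted p under 0.05, grey dots are not called, and the black line is the mean of the list, drawn thick where the camera adjusted p was under 0.05. All 29 interferon-response genes lie below 0 in Id2-HPC against E2A-deficient, and 27 of 29 are called above 0 in E2A-deficient against EBF-deficient.

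Both comparisons with Id2-HPC shared many genes, among them Akr1c13, higher by 3.72 and 4.17, and Notch1, lower with differences of −3.13 and −3.12. In all, 3269 genes were called in the same direction in both, 2006 higher and 1263 lower in Id2-HPC, where independent lists of these sizes would share 673 and 365. With a difference of at least 2-fold in both, 134 genes were higher and 109 lower, against 5.5 and 8.1 for independent lists. Because both comparisons use the same Id2-HPC arrays, 6 arrays without any group difference were also simulated, and the highest overlap in 100 draws was 1 gene. With nothing changed, hardly any gene is called. That overlap therefore cannot show how many shared calls come from the shared arrays. Across genes, which are not independent replicates, the log2 differences correlated at 0.46 against 0.5 in the simulation, and their covariance was 0.0911 against 0.0028. The correlation thus did not exceed the value that shared arrays alone gave. The Id2-HPC arrays are too few to be split into parts of 2 arrays each. How many of the shared calls come from the shared arrays, including any such technical difference, is therefore not known.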

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

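All tests of explanations in this part were chosen only after the results were seen.

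The poly-A control transcripts lie outside the gene comparisons and were above the other 4 arrays in both Id2-HPC arrays, by 5.29 log2 units for dap, 1.97 for lys, 2.52 for phe and 3.07 for thr. Between the 2 comparisons with Id2-HPC, 591 genes were called in opposite directions. In a single fit, such opposite calls already imply a difference between E2A-deficient cells and those labelled EBF-deficient, so the call in that comparison adds no evidence here.

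Of 35 stromal genes, 18 were called higher in Id2-HPC arrays in each comparison, while Pdgfrb and Igfbp4 were lower than in the arrays labelled EBF-deficient; both list calls were lost with an estimated correlation (adjusted p = 0.0599 and 0.065). If RNA of the S17 feeder cells were the source, stromal genes that are dim elsewhere should be higher together. Of 21 such members, 10 had a probe set called higher in both comparisons (Col1a2, Cav1 and Lox among them), while 11 did not, including Col1a1 and Cxcl12. Over all 35 members, dim or not, 21 had such a probe set and the rest did not. Cald1 was at 7.36 in Id2-HPC arrays, 4.5 in E2A-deficient arrays and 4.49 in those labelled EBF-deficient. Sparc was at 7.04, 5.18 and 5.15 in the same order. Another probe set of each was brighter in the other 4 arrays, so neither counted as dim. Because the profile of S17 cells is not in these data, that mix of members leaves feeder RNA open, and all 3 cultures were grown on S17. Separate labelling of the Id2-HPC RNA stays open as well: the poly-A controls differed by a mean of 3.21 log2 units, and no group holds arrays with and without them, so labelling run and cell type cannot be told apart for these genes. Expression of such genes by the Id2-HPC cells themselves was not tested.

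Ebf1 was higher in the arrays labelled EBF-deficient. B cells that express Ebf1 together with 8 B-cell genes, from Cd79a to Pax5, are argued against, since their median difference was −0.02 (SD 0.18 over the genes, highest 0.34). Cells without these genes are not covered. Some other B-lineage genes were higher in the arrays labelled EBF-deficient. Id2-HPC and E2A-deficient arrays differed from them by −1.66 and −1.63 for Ighm and by −2.10 and −2.01 for Spib. Of 29 early B-lineage genes, 14 and 13 were lower than in these arrays, and 4 and 2 higher. Ebf1 itself is in this list and in both counts of lower genes. A single cross-hybridising probe set is argued against as well, since all 5 Ebf1 probe sets were higher, the smallest difference being 2.78. RNA still made from a disrupted Ebf1 allele and a wrong label on both arrays stay open; neither was tested, as the part of Ebf1 that was removed is not given in the sources used here. No biological explanation other than the group itself was tested.

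Xist and Y-linked transcripts were present together in the arrays labelled EBF-deficient. Id2-HPC cells mixed into these cultures would have to make up 50.6% to supply Eif2s3y; of 5146 genes above 200 intensity units in Id2-HPC arrays, 29 lay under 0.5 times the level that this share requires, which argues against it. E2A-deficient cells as the source of Xist would have to make up 78.5%, and 133 of 4921 genes lay under 0.5 times that level, which argues against it too. RNA of S17 feeder cells stays open, because their profile is not in these data: of 35 stromal genes only Igfbp4 and Pdgfrb were called higher than in both other groups, and the median difference was −0.05 against E2A-deficient and −0.24 against Id2-HPC arrays. A culture from mice of both sexes stays open and was not tested, and no biological explanation was tested, because the labels give no sex.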

How the results depend on the processing

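Fits without X- and Y-linked genes and without stromal genes were chosen after seeing the data. Counts of called genes are in the order Id2-HPC against EBF-deficient, Id2-HPC against E2A-deficient, E2A-deficient against EBF-deficient, and same direction in both Id2-HPC comparisons. They moved by over 1.5 times under 2 settings: with all named probe sets as separate rows (34945 tested) they were 11602, 11190, 9669 and 6397, because more rows were tested, and with an added 2-fold threshold 629, 780, 741 and 243. Leaving out each array in turn gave 4854 to 6410, 4744 to 5960, 4443 to 5553 and 2429 to 3051; the lone array of a group is then assumed to vary like the others. Without X- and Y-linked genes the counts were 5928, 5857, 5521 and 3177, and without stromal genes 6079, 6034, 5714 and 3253. Without quantile normalization the calls higher in the first group made up 62.2%, 67.2% and 44.7%, against 56.7%, 58.5% and 48.8%.

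The deviations of samples with the same replicate number correlated at −0.11 (Id2-HPC with E2A-deficient), −0.19 (Id2-HPC with EBF-deficient) and 0.22 (E2A-deficient with EBF-deficient), so the numbers do not pair the samples. With the replicate number as a block, 6080, 6020, 5668 and 3232 genes were called, and no call of a named gene or list changed.

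Of 4657 values of named genes under alternatives, 4530 stayed on the same side of the threshold, 110 lost the call and 9 gained it. The remaining 8 had the opposite sign with a call in the main fit, the alternative or both, and are termed reversed. Signs were not compared where neither fit called the gene. As the mean of all probe sets, Tcf12 (−0.35) and Mycn (−1.28) reversed in Id2-HPC against E2A-deficient, and Mycn (1.08) and Notch1 (0.16) in E2A-deficient against EBF-deficient; the setting itself brings in other probe sets. Among the reversed genes, only Mycn was called in both directions. Without probe sets shared between transcripts, Acta2 reversed in Id2-HPC against EBF-deficient (−0.04) and E2A-deficient against EBF-deficient (−0.07), and Foxo1 (0.47) and Rab27b (−0.01) in Id2-HPC against E2A-deficient, on another probe set. That Acta2 probe set read 4.57 to 4.65 over the groups, near the lower end of the scale, so its change of sign decides nothing. With fry, which does not compare a list with other genes, 11 list results gained a call in the direction of camera. Among list results called by fry or camera, 2 turned direction with fry. They were early B-lineage genes in Id2-HPC against E2A-deficient (median −0.04) and dendritic-cell genes in E2A-deficient against EBF-deficient (median 0.10). The cause was not tested. Of 20 list calls among 39, 4 held with an estimated correlation and 16 were lost. In Id2-HPC against EBF-deficient, the estimate for the lost mature B-cell list was 0.124, above the preset 0.01. It was below the preset for the lost cell-cycle (−0.001), early B (−0.02) and interferon-response (−0.031) lists. A higher correlation between genes therefore does not account for these latter losses. Dim genes are limited by the signal over background, for which no measure was used here.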

Other observations

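The genes in this part were chosen after their values were seen; the tests of neighbouring genes were set before their results.

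Receptors for the cytokines of the culture medium differed between the groups. Il7r, the interleukin 7 receptor chain, was at 7.69 ± 0.11 in Id2-HPC arrays, 9.68 ± 0.06 in E2A-deficient arrays and 11.33 ± 0.07 in the arrays labelled EBF-deficient (SD, 2 arrays each). Flt3, the receptor of Flt3 ligand, was at 9.86 ± 0.22, 11.52 ± 0.33 and 11.07 ± 0.15, and Kit, the receptor of stem cell factor, at 8.54 ± 0.04, 8.01 ± 0.08 and 9.68 ± 0.01. All 3 receptors were called lower in Id2-HPC than in the cells labelled EBF-deficient, whereas against E2A-deficient cells Il7r and Flt3 were lower and Kit was higher by 0.53 ± 0.07. Of 33 measured Hox genes, 6 reached at least 1 log2 unit above the median of all probe sets in a group. Among them, Hoxa9, a regulator of progenitor self-renewal, was highest in the cells labelled EBF-deficient (12.58 ± 0.03, against 11.69 ± 0.13 in Id2-HPC and 11.40 ± 0.09 in E2A-deficient cells), and Hoxa5 (9.08), Hoxa7 (8.53) and Hoxa10 (6.75) were also highest there. The other two did not follow: Hoxb4 was lowest there (5.77, against 6.44 in Id2-HPC and 6.55 in E2A-deficient cells), and Hoxc9 was not called in any comparison (6.23, 6.25 and 6.38).

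Mycn, a growth-promoting transcription factor gene, gave different answers on its 3 probe sets. The brightest on average was at 10.57 in Id2-HPC arrays, 9.18 in E2A-deficient arrays and 11.25 in the arrays labelled EBF-deficient, and a dim probe set followed it (6.09, 5.57 and 6.23), whereas the third was at 6.26, 11.99 and 6.02 in the same order. Among 9010 genes with several probe sets, those with probe sets called at least 2-fold in opposite directions were Rad23b in Id2-HPC against EBF-deficient, Mycn and Zdhhc20 in Id2-HPC against E2A-deficient, and Mycn and Xaf1 in E2A-deficient against EBF-deficient.

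A targeted allele can carry neighbouring genes of the strain in which it was made, which may then differ in 1 group alone. Among the 100 measured genes nearest to Tcf3, 2 (Cnn2 and Prtn3) were called at least 2-fold in the same direction in E2A-deficient cells against both other groups, against 381 of 17931 genes elsewhere (2.1%; two-sided Fisher's exact p = 1; exact binomial 95% interval of the share 0.2% to 7%). Among the 100 nearest to Ebf1, 1 (Pttg1) was called in this way in the cells labelled EBF-deficient, against 220 of 17931 elsewhere (1.2%; two-sided Fisher's exact p = 1; interval 0% to 5.4%). Neither window held a higher share, and with 100 genes the intervals are too wide to exclude such genes.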
